A study of Mus musculus with 3 samples.

How the data were processed

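Total RNA from male gonads of mouse embryos at embryonic day 14.5 was measured on Agilent one-colour 44K mouse arrays. The embryos were of a mouse line that the labels name MCH. There were 3 genotypes with 2 arrays each: wild type, Cyp26b1 knockout, and knockout of both Cyp26b1 and Stra8 (double knockout). The labels' protocols state that gonads were dissected in cold buffered saline and frozen in an RNA preservative, and that 0.20 µg RNA was labelled with Cy3. The series design text says that duplicates were biological, but nothing says whether an array held 1 embryo or a pool. The p-values measure only the spread between these arrays.

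The authors deposited 1 scanner file per array, whose values are spot intensities on a linear scale. Spots were read with Agilent Feature Extraction 9.5, per the submitters' processing notes, and version 9.5.3.1, per the file headers. The processed signal in these files had been background-subtracted and detrended by that software, per the file headers. Upper quartiles from 997 to 1532 showed that it had not been scaled between arrays. Dim spots held small positive values in place of negative ones. The authors also deposited a value table with 1 column per genotype, whose values behaved as a linear ratio. The differences between its log2 columns matched the differences between genotype means of the log2 processed signals, with a Pearson r across 18971 probes of 0.999997 for Cyp26b1 knockout against wild type and slopes of 0.99991 to 0.99996. They were shifted by 0.10 for Cyp26b1 knockout against wild type, by -0.20 for double knockout against wild type and by -0.30 for double knockout against Cyp26b1 knockout. The table's column medians were 0.99979 for wild type, 1.12 for Cyp26b1 knockout and 0.959 for double knockout. The direction of the table was therefore settled, while its centring reference and its scaling between arrays stayed unknown. How the authors tested differences is not given in the sources used here.

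The main values were log2 processed signals minus the 75th percentile of each array. Control spots and spots marked as outliers in their signal were left out, spots of one probe were averaged, and 25 probes with no usable spot on some array were dropped. The scanner files give accessions and no gene names. Names came from accessions matched, without versions, to an NCBI RefSeq gene table of assembly GRCm38.p6. Of 41174 probes, 23374 matched 1 gene symbol, 0 matched several and 17800 matched none. The arrays' own annotation uses an older genome build, per the file headers, so no coordinates are given. Each gene was represented by its probe with the highest mean over the 6 arrays. A feature was tested if it was well above background on both arrays of at least 1 genotype, which left 21552 features, of which 13294 had a gene symbol.

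Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) in one fit over all 6 arrays, with 3 residual and 4.34 prior degrees of freedom. All p-values are two-sided, adjusted by Benjamini-Hochberg, with a threshold of 0.05. Errors of log2 changes are standard errors of that fit with n = 2 arrays per genotype. Where a probe was not well above background on either array of a genotype, only a bound on the fold is given. The bound sets the brighter mean against the lowest signal among probes well above background, or the dim probe's own signal if higher. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with fry as a self-contained alternative, and adjusted over the lists of a comparison. With an estimated correlation, camera is also limited to the 3 residual degrees of freedom of the fit. That setting is therefore stricter whatever the correlation of a list. Stra8 is a member of the meiotic prophase and retinoic acid lists, and Cyp26b1 of the latter, so the targeted genes enter these counts and tests. With 2 arrays per genotype, an exact permutation test could not reach the threshold.

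The comparisons, tests, gene lists, the other settings tried and the rule for naming genes were fixed before the data were examined. For each comparison the rule takes both targeted genes, the 6 largest rises and 6 largest falls among called named genes whose arrays separate the genotypes, and up to 3 members of each list with the smallest adjusted p. Where no member passed, it takes 2. Changes known only as a bound have no order and were not ranked, a condition the written rule did not state. A gene taken in one comparison is also quoted in the others. Some genes that the rule takes are not reported here.

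The fit was tested on 20 simulated sets per comparison, each with 21552 features, of which 200 were changed. With each feature's own estimated variance, Cyp26b1 knockout against wild type recovered 39.0% of 1.5-fold changes, 71.6% of 2-fold changes and 97.1% of 4-fold changes. False calls were then 8.32% of all calls for that comparison, 7.80% for double knockout against wild type and 8.41% for double knockout against Cyp26b1 knockout, above the nominal level. With variances drawn from limma's fitted prior, Cyp26b1 knockout against wild type recovered 14.9%, 53.4% and 87.6% of changes of these sizes. The shares of false calls were then 5.47%, 5.61% and 5.19%. Where few features change, adjusted p-values near the threshold may thus be somewhat too small if real variances depart from that prior. In the data, 51.2% of features were called for Cyp26b1 knockout against wild type. The share was 12.0% for double knockout against wild type and 43.1% for double knockout against Cyp26b1 knockout. Sets with such large shares changed were not simulated, so the recovery and false calls given here need not hold for the data. In the same simulations 100% of lists with all 20 members raised 1.5-fold reached an unadjusted camera p under the threshold. Of unchanged lists, 1.25% to 2.5% did. Features were drawn independently, so lists of correlated genes or of mixed directions were not tested.

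The share of spots well above background was 62.6% to 69.2% per array, and the number of arrays limits the precision. The 3 slides held 1 genotype each. The Cyp26b1 knockout slide was scanned on another day than the other 2 slides, so slide and genotype cannot be told apart. Alternatives covered background correction, normalization, the filter, a floor, the choice of probes, the eBayes prior, the arrays in the fit, a replicate block, each array left out, a minimum fold, and the list test. The planned background correction by normexp names a mean signal column that the files used here do not hold, so the median spot signal was used. That fit was upset on 2 arrays by a few spots of extreme local background, and a second fit without the spots marked by the scanner software was added. A setting with the shifts of the authors' table was also added after the data were seen.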

Results

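Gene expression was compared in male gonads of mouse embryos at embryonic day 14.5 from 3 genotypes, with 2 arrays each. Cyp26b1 encodes an enzyme that degrades retinoic acid, and Stra8 encodes a retinoic acid-responsive factor needed for entry into meiosis. The design asks what changes when Cyp26b1 is lost, and which of these changes differ when Stra8 is lost as well. Within a genotype the 2 arrays had a Pearson r of 0.994 to 0.996 across the 18971 features well above background on all arrays, and their differences had SDs of 0.243 (wild type), 0.298 (Cyp26b1 knockout) and 0.290 (double knockout) on the log2 scale.

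The targeted genes were examined first. The single Cyp26b1 probe had a mean log2 signal, relative to the 75th percentile of its array, of 3.93 ± 0.14 (SD, n = 2) in wild type, 4.05 ± 0.31 in the arrays labelled Cyp26b1 knockout and 4.01 ± 0.14 in those labelled double knockout. These levels gave limma adjusted p values of 0.552 and 0.771 against wild type. The single Stra8 probe stood at 3.07 ± 0.94 in wild type, 7.11 ± 0.11 in the arrays labelled Cyp26b1 knockout and 6.06 ± 0.11 in those labelled double knockout. Single arrays gave Cyp26b1 4.03 and 3.83 in wild type, 4.27 and 3.83 in Cyp26b1 knockout, and 4.11 and 3.91 in double knockout. They gave Stra8 3.73 and 2.41, 7.19 and 7.04, and 5.98 and 6.14 in the same order. Stra8 was thus brighter in the arrays labelled double knockout than in wild type, by 2.98 ± 0.36 (adjusted p = 0.00383). It was dimmer than in the arrays labelled Cyp26b1 knockout, by a log2 change of -1.05 ± 0.36 (adjusted p = 0.0483). The last call was lost without any 1 of the 4 arrays compared (adjusted p from 0.0995 without double knockout replicate 2 to 0.162 without Cyp26b1 knockout replicate 1), and for example with eBayes without the trend (adjusted p = 0.0999). Where these probes lie relative to the deleted parts is not given in the sources used here, and a probe outside the deleted part checks nothing. Genotypes below are those of the labels, and every direction is between arrays so labelled.

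Y-linked genes were measured on all arrays as a check of the labels. Relative to wild type, Ddx3y fell by 0.93 on the log2 scale in the Cyp26b1 knockout arrays (adjusted p = 0.00148), and Uty, Kdm5d and Eif2s3y did not pass the test in either knockout. Ddx3y rose by 0.77 in the double knockout against the Cyp26b1 knockout. Of the 5 genes of this list 4 were tested. Xist was on the array, but its probe was not well above background on both arrays of any genotype. The list had a camera adjusted p of 0.725, 0.878 and 0.922 in the 3 comparisons, which compares genotypes and does not test sex.

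In the arrays labelled Cyp26b1 knockout, 18 of 23 meiotic prophase genes and 16 of 27 retinoic acid signalling genes rose against wild type, and 15 of 19 genes of male germ cell differentiation fell. The targeted gene Stra8 is among the genes that rose in both of the first 2 lists. As lists these had camera adjusted p = 1.39e-05, 0.00565 and 0.000231 at the preset correlation. With an estimated correlation they had adjusted p = 0.437, 0.426 and 0.426. Cyp26a1, another retinoic acid-degrading enzyme, rose by 4.84 ± 0.32 (log2 ± SE, n = 2 arrays per genotype). Dnmt3l, a cofactor of DNA methylation in male germ cells, fell by 7.03 on the log2 scale (SE 0.38), a 131-fold fall and the largest measured among named genes. Other large rises were those of Fabp4, a fatty acid-binding protein (4.60), the Nodal antagonist Lefty1 (4.27), Stra8 (4.04), the germ cell transcription factor Sohlh2 (3.97) and the lysophosphatidic acid receptor Lpar3 (3.95). The other large falls were in Clca1 (-4.99), the bicarbonate transporter Slc4a7 (-4.86), the homeobox gene Dbx2 (-4.85), the ciliary gene Drc1 (-4.60) and the vesicular GABA transporter Slc32a1 (-4.31). The fall of Slc4a7 rests on its brightest probe, since its other probes differed by -1.21 and -0.37. Cyp26a1 and Lpar3 were well above background on 1 of 2 wild-type arrays and Clca1 on 1 of 2 Cyp26b1 knockout arrays, so the sizes of these changes are uncertain.

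Of 23 measured meiotic prophase genes, 18 rose, 1 fell and 4 did not pass the test (adjusted over the list alone, 18 rose and 2 fell). Rec8, a meiotic cohesin subunit, rose by 2.76 ± 0.16, Msh5, a crossover protein, by 2.25 ± 0.19, and Ugt8a by 2.84 ± 0.24. Msh5 (0.63, adjusted p = 0.568) and Ugt8a (1.19, adjusted p = 0.0550) were not called with the first of the normexp background corrections. That fit was upset on 2 arrays by spots of extreme local background. With the second normexp fit no named gene lost its call in any comparison. The list had a camera adjusted p of 1.39e-05 (adjusted p = 0.437 with an estimated correlation). Of 27 retinoic acid signalling genes, 16 rose and 4 fell, the same numbers as when adjusted over the list alone. The receptor gene Rarb rose by 1.95 ± 0.10 and the synthesis enzyme Aldh1a1 changed by -1.20 ± 0.09. This list had an adjusted p of 0.00565 (adjusted p = 0.426 with an estimated correlation).

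Of 19 genes of male germ cell differentiation and the piRNA pathway, which silences transposons, 15 fell and 1 rose (adjusted over the list alone, 16 fell and 2 rose). Egr4 changed by -2.01 ± 0.08, Ddx25 by -1.93 ± 0.10 and Dnd1, an RNA-binding germ cell factor, by -2.01 ± 0.13. Nanos2, a male fate regulator, changed by -2.93 ± 0.26, Morc1 by -3.30 and Tdrd1 by -2.01, all 3 named after their values were seen. The list had an adjusted p of 0.000231 (adjusted p = 0.426 with an estimated correlation). General germ cell markers went both ways, with 9 of 22 rising and 8 falling, and the list did not pass (adjusted p = 0.509). Among them the X-linked homeobox genes Rhox6 and Rhox9 rose by 2.91 and 2.46, values that are uncertain because members of that family have near-identical copies.

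Among pluripotency and Nodal signalling genes, 5 of 23 rose and 4 fell (adjusted p = 0.725). Dppa4 changed by -2.07 ± 0.20. Sertoli cell markers were mixed, with 5 of 28 higher and 10 lower (adjusted p = 0.872). In that list Dmrt1, which germ cells also express, rose by 2.86 ± 0.20 and Hsd17b1, a steroid-converting enzyme, changed by -2.85 ± 0.22. Ptgds changed by -0.80. Of 18 fetal Leydig cell genes, 9 fell and 3 rose (adjusted p = 0.120), with Hsd17b7 at -1.86, Fdx1 at -0.99 and Cited4 at 2.15. A second probe of Hsd17b7 differed by -0.56. The Leydig list passed the test only without Cyp26b1 knockout replicate 2 among the arrays left out (adjusted p = 0.0497, against adjusted p = 0.704 with all arrays and an estimated correlation). Of 20 fetal ovarian somatic genes, 7 rose and 10 fell (adjusted p = 0.725). Wnt4, a signal of ovarian development, rose by 1.23 ± 0.09, Msx2 changed by -1.93, and Dapl1, not well above background in the knockout, was at least 3.46-fold lower.

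Of 35 cell cycle genes, 13 rose and 5 fell (adjusted p = 0.118). The replication factors Mcm3 and Mcm2 rose by 1.30 and 0.83, and the spindle checkpoint gene Bub1b by 0.95. This list passed without Cyp26b1 knockout replicate 2 (adjusted p = 0.0370), and with all arrays had adjusted p = 0.704 with an estimated correlation. Of 15 cell cycle inhibitors, 2 rose and 6 fell (adjusted p = 0.378), with Cdkn2b at -1.92, Cdkn1c at -0.71 and Gadd45b at 0.89. Of 24 p53 and apoptosis genes, 4 rose and 8 fell (adjusted p = 0.725), with Pmaip1 at -1.85, Fas at -1.58 and Casp8 at 0.78.

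Markers of other cell types that a dissected gonad could hold were tested in the same way. Of 17 endothelial genes, 9 rose and 3 fell (adjusted p = 0.0460, and adjusted p = 0.704 with an estimated correlation). Pecam1 rose by 1.58, Nos3 by 0.87 and Esam by 0.64. That list's call was also lost without wild-type replicate 2 (adjusted p = 0.0948), Cyp26b1 knockout replicate 1 (0.0643), double knockout replicate 1 (0.0520) or double knockout replicate 2 (0.0522). Of 24 interstitial and peritubular genes, 7 rose and 8 fell (adjusted p = 0.725), and Des rose by 1.10. Pdgfra and Lhx9 differed by -1.07 and -0.82 at their brightest probe but by 0.74 and 0.76 at their other probe, so no direction is given for them. Of 18 genes of the mesonephros and duct epithelium, 2 rose and 6 fell (adjusted p = 0.725), with Upk3b at 0.97 and Krt8 at -0.67. Osr1 differed by -0.70 at one probe and 0.04 at the other. Of 19 blood cell and macrophage genes, 2 rose and 3 fell (adjusted p = 0.946), with C1qa at 0.67 and Csf1r at 0.66. Alas2 changed by -0.71, a call lost without wild-type replicate 1, wild-type replicate 2 or Cyp26b1 knockout replicate 1 (adjusted p = 0.144, 0.0598 and 0.0846). It was also lost with quantile normalization, the authors' scaling, no filter on dim probes or no eBayes trend (adjusted p from 0.0509 to 0.0691).

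Adjusted over the list alone, p53 and apoptosis genes counted 4 higher and 6 lower, interstitial genes 8 and 8, and blood genes 2 and 0. For the lists not named here or above with such a count, it equalled that over all features. In the blood list the mean change was -0.09 while camera's direction was up, and in the pluripotency list the median was -0.02 while the mean was 0.22.

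In total, 4599 of 21552 features were higher and 6443 lower in the Cyp26b1 knockout arrays (limma, adjusted p below the threshold), which is 51.2% of those tested. Among genes with a symbol, 3126 were higher and 4008 lower. Of the calls, 41.7% were higher, against 51.7% under the scaling of the authors' value table. At 2-fold or more, 1502 were higher and 2002 lower. Without wild-type replicate 2 the number higher was 3062. Besides Msh5 and Ugt8a, the first normexp correction did not call Dapl1, Ptgds (-0.50), Fdx1 (-0.78), Cdkn1c (-0.44), Fas (-1.49), Des (0.44), Nos3 (0.43), C1qa (0.089) and Csf1r (0.23), with adjusted p from 0.0987 to 0.867. With the second normexp fit, made without marked spots, these calls were kept. All Cyp26b1 knockout arrays lay on 1 slide scanned on a day of its own, so slide, scan day and genotype cannot be told apart.

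**Figure D1:**
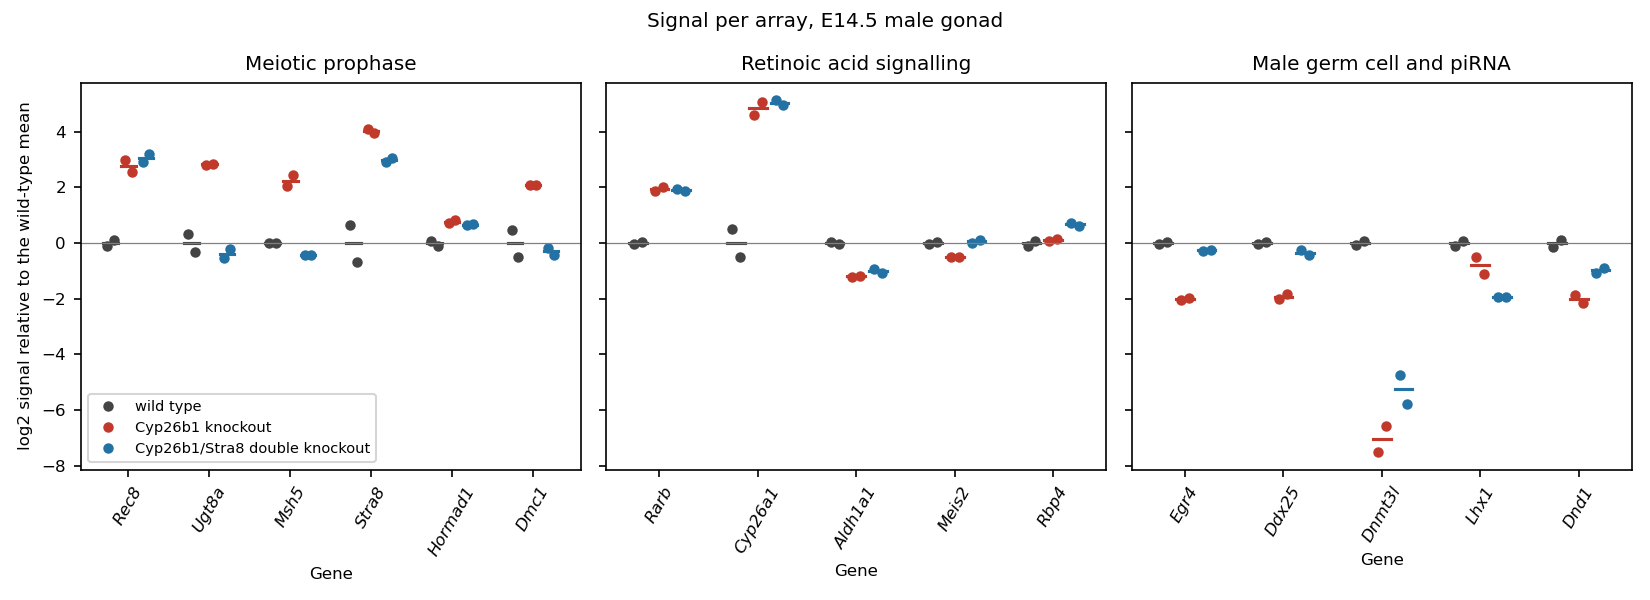
Log2 signal of each array relative to the wild-type mean, for genes that the naming rule took from 3 lists, without genes not reported here. Points are arrays and short lines are genotype means. The retinoic acid genes Cyp26a1 and Rarb were raised in both knockouts, by 4.84 and 1.95 in the Cyp26b1 knockout. Ugt8a, Msh5 and Dmc1 were raised by 2.84, 2.25 and 2.10 there and stood at -0.37, -0.44 and -0.29 in the double knockout. The other meiotic genes shown were higher than wild type in the Cyp26b1 knockout and the double knockout: Rec8 (2.76 and 3.06), Stra8 (4.04 and 2.98) and Hormad1 (0.77 and 0.66).

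In the arrays labelled double knockout, 13 of 27 retinoic acid signalling genes rose against wild type, 1 fell and 13 did not pass the test, and 5 of 19 male germ cell genes fell. As lists these had camera adjusted p = 9.79e-06 and 0.00244 at the preset correlation. With an estimated correlation they had adjusted p = 0.180 and 0.644. Cyp26a1 rose by 5.05 ± 0.32 and Rarb by 1.90 ± 0.10. Fabp4 (5.15), Lpar3 (4.75), the chloride channel protein Clic6 (4.05) and Lhx8, a regulator of oocyte genes (3.52), were other large rises. Dnmt3l fell by 5.25 on the log2 scale (SE 0.38). The next largest falls measured among ranked named genes were in Jaml (-3.20), the oocyte gene Padi6 (-3.09), Myh2 (-3.07), Cpn1 (-3.06) and Ucma (-2.98). Clca1 stood at -0.99 in wild type and -6.23 in the double knockout, where it was well above background on 0 arrays. Its change is known only as a bound and was not ranked. The calls of Myh2, Cpn1 and Ucma were lost without either wild-type array. Padi6, Myh2 and Cpn1 were well above background on 1 of 2 double knockout arrays.

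Of 27 retinoic acid signalling genes, 13 rose and 1 fell, as when adjusted over the list alone (adjusted p = 9.79e-06, and adjusted p = 0.180 with an estimated correlation). Of 23 meiotic prophase genes, 6 rose, among them the targeted gene Stra8, and 1 fell (adjusted over the list alone, 11 and 3), and the list did not pass (adjusted p = 0.0813). It passed without wild-type replicate 1 (adjusted p = 0.00806) or double knockout replicate 1 (adjusted p = 0.0241), and with all arrays had adjusted p = 0.875 with an estimated correlation. Rec8 rose by 3.06 ± 0.16 and Hormad1, a chromosome axis protein, by 0.66, a call lost without wild-type replicate 2. Ugt8a, Msh5 and the recombinase gene Dmc1 had log2 changes of -0.37, -0.44 and -0.29 and did not pass the test. Of 19 male germ cell genes, 5 fell and 0 rose (adjusted over the list alone, 8 and 2), with an adjusted p of 0.00244 (adjusted p = 0.644 with an estimated correlation). Lhx1, which is also a member of the mesonephros and duct list, changed by -1.94. Dnd1 changed by -0.97 and was not called without wild-type replicate 2.

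Of 22 general germ cell markers, 6 rose and 3 fell (adjusted p = 0.151, and adjusted p = 0.0241 without double knockout replicate 1). With all arrays that list had adjusted p = 0.875 with an estimated correlation. The receptor gene Kit rose by 1.47 ± 0.13 and Taf7l by 1.30 ± 0.13. Of 23 pluripotency and Nodal genes, 2 rose and 3 fell (adjusted p = 0.724). Nr0b1, which is also a member of the ovarian somatic list, rose by 1.26 ± 0.11. Dppa4 (-1.34) was called with all arrays and not without wild-type replicate 2. Of 28 Sertoli cell genes, 5 rose and 6 fell (adjusted p = 0.820), with Hsd17b1 at -2.89, Hsd17b3 at -1.68 and the junction gene Cldn11 at 1.55. Of 18 Leydig genes, 1 rose and 4 fell (adjusted p = 0.240), with Cited4 at 1.68. Star (-0.97) was not called without either wild-type array, nor Hsd17b7 (-0.64) without wild-type replicate 2. Of 20 ovarian somatic genes, 5 rose and 3 fell (adjusted p = 0.724), with Sp5 at 1.27 and Wnt4 at 0.76.

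Of 35 cell cycle genes, 2 rose and 0 fell (adjusted p = 0.0891). Of 15 inhibitors, 2 rose and 2 fell (adjusted p = 0.889), with Cdkn2b at -1.33 and Gadd45b at 0.63, and of 24 p53 and apoptosis genes 1 rose and 1 fell (adjusted p = 0.724). Of 17 endothelial genes, 5 rose and 0 fell (adjusted p = 0.00244, and adjusted p = 0.693 with an estimated correlation). Of 24 interstitial genes, 3 rose and 0 fell (adjusted p = 0.732), with Lhx2 at 1.25 and Lum at 1.04. Of 18 mesonephros and duct genes 1 rose and 2 fell (adjusted p = 0.277), and of 19 blood genes 1 rose and 1 fell (adjusted p = 0.566).

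Adjusted over the list alone, the counts higher and lower were 3 and 4 for pluripotency and Nodal genes, 8 and 3 for general germ cell markers, 6 and 9 for Sertoli cells, 2 and 8 for Leydig cells and 6 and 5 for ovarian somatic cells. They were 6 and 4 for p53 and apoptosis, 2 and 4 for mesonephros and ducts, 7 and 0 for endothelial cells and 1 and 0 for the sex check, and unchanged for inhibitors, cell cycle, interstitial and blood genes. Mean and median had opposite signs for ovarian somatic genes (0.06 and -0.03), p53 genes (-0.03 and 0.04), interstitial genes (0.06 and -0.03) and blood genes (-0.04 and 0.18). The interstitial median was 0.011, of the same sign as the mean, with members known only as bounds set at those bounds.

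In total, 1170 features were higher and 1413 lower in the double knockout than in wild type, 12.0% of those tested, and 348 and 610 at 2-fold or more. These counts rested heavily on the wild-type arrays. Without wild-type replicate 2 they were 272 and 259, without wild-type replicate 1 they were 331 and 334, without double knockout replicate 1 they were 683 and 856, and without double knockout replicate 2 they were 568 and 718. Of the genes named above as changed, the first normexp correction did not call Jaml (-1.87), Padi6 (-1.67), Myh2 (-1.36), Cpn1 (-1.43), Ucma (-1.67), Hormad1 (0.57), Lhx1 (-1.24) and Hsd17b7 (-0.47), with adjusted p from 0.0788 to 0.899. That correction was upset on wild-type replicate 2 and double knockout replicate 1, and the second normexp fit kept these calls. The share higher was 45.3%, against 71.0% with median scaling and 13.5% under the authors' scaling, so the balance of small rises and falls depends on the scaling. The median log2 change of all features was -0.02, against 0.12 and -0.22 under those scalings.

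The comparison of the double knockout with the Cyp26b1 knockout bears on the loss of Stra8 without functional Cyp26b1. In the double knockout arrays 12 of 23 meiotic genes fell, 2 rose and 9 did not pass the test, and 13 of 19 male germ cell genes rose and 2 fell. The targeted gene Stra8 is among the 12 that fell. The 2 lists had camera adjusted p = 0.00101 and 0.00377 at the preset correlation, and both had adjusted p = 0.968 with an estimated correlation. Ugt8a changed by -3.21 ± 0.24, Msh5 by -2.69 ± 0.19 and Dmc1 by -2.39 ± 0.29. Msh5 was not called with the first normexp correction (-1.27, adjusted p = 0.152). Of 23 meiotic prophase genes, 12 fell and 2 rose (adjusted over the list alone, 13 and 2), with an adjusted p of 0.00101 (adjusted p = 0.968 with an estimated correlation). Rec8 did not pass the test, at 0.29 ± 0.16, and a second probe differed by -0.28. M1ap, a meiotic gene, changed by -3.69 ± 0.24, the largest fall measured among named genes. Other large falls were in Inca1 (-3.39), Lypd4 (-3.07), the class II antigen gene H2-Ab1 (-2.99) and Timmdc1 (-2.87).

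Of 19 male germ cell genes, 13 rose and 2 fell, as when adjusted over the list alone (adjusted p = 0.00377, and adjusted p = 0.968 with an estimated correlation). Egr4 rose by 1.76 ± 0.08, Ddx25 by 1.59 ± 0.10 and Dnd1 by 1.04 ± 0.13. Dnmt3l rose by 1.78 ± 0.38 from its low level in the Cyp26b1 knockout. Without a filter on dim probes the list's call was lost (adjusted p = 0.131). The largest rises were in Slc4a7 (5.44), Sly (3.46), Prok2 (3.23), Car6 (2.77), the imprinted gene Phlda2 (2.76) and Fbxw13 (2.60). Sly belongs to a multicopy family and is uncertain, and the other probes of Slc4a7 differed by 0.53 and 0.15. Prok2 was well above background on 1 of 2 Cyp26b1 knockout arrays.

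Of 27 retinoic acid signalling genes, 8 rose and 5 fell, and the list did not pass (adjusted p = 0.922). Rbp4 and Meis2 rose by 0.57 and 0.57, with Rbp4 not called under the authors' scaling (adjusted p = 0.0583), while Cyp26a1 (0.21) and Rarb (-0.04) did not pass the test. Of 22 general germ cell markers, 8 rose and 6 fell (adjusted p = 0.993), with Nanos3 at 1.95, Rhox6 at -2.34 and Rhox9 at -1.69. Of 23 pluripotency and Nodal genes, 4 rose and 2 fell (adjusted p = 0.993), with Lefty2 at -1.38 and Klf4 at 0.79. Of 28 Sertoli genes, 8 rose and 4 fell (adjusted p = 0.993), with Dmrt1 at -1.64, Hsd17b3 at -0.88 and Cldn11 at 0.90. Of 18 Leydig genes, 8 rose and 3 fell (adjusted p = 0.445), with Hsd17b7 at 1.22 at its brightest probe and 0.088 at another. Of 20 ovarian somatic genes, 10 rose and 3 fell (adjusted p = 0.218), with Msx2 at 1.20 and Lgr5 at 0.89.

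Of 35 cell cycle genes, 12 fell and 5 rose (adjusted p = 0.409), with Mcm3 at -1.10, Ccne2 at -1.15 and Bub1b at -0.80. Of 15 inhibitors, 3 rose and 1 fell (adjusted p = 0.409), and of 24 p53 and apoptosis genes 9 rose and 3 fell (adjusted p = 0.531), with Fas at 0.96. Of 17 endothelial genes, 5 rose and 5 fell (adjusted p = 0.993), with Pecam1 at -1.27. Of 24 interstitial genes, 6 rose and 7 fell (adjusted p = 0.993), with Dcn at 1.08. Of 18 mesonephros and duct genes, 3 rose and 3 fell (adjusted p = 0.887), and of 19 blood genes 3 rose and 3 fell (adjusted p = 0.993).

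Adjusted over the list alone, the counts higher and lower were 14 and 4 for ovarian somatic genes, 3 and 0 for inhibitors, 2 and 3 for mesonephros and ducts and 3 and 2 for blood genes, and for lists without such a count here or above they equalled those over all features. Mean and median had opposite signs for pluripotency genes (-0.08 and 0.14), cell cycle genes (-0.12 and 0.04), endothelial genes (-0.025 and 0.022) and retinoic acid genes (-0.0054 and 0.16). For general germ cell markers camera's direction was down, with a mean of 0.03.

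In total, 5502 features were higher and 3790 lower in the double knockout than in the Cyp26b1 knockout, 43.1% of those tested, and 867 and 1250 at 2-fold or more. The share higher was 59.2%, against 70.7% with median scaling and 22.8% under the authors' scaling. The median log2 change of all features was 0.09, against 0.21 and -0.21 under those scalings. Besides Msh5, the genes named above that lost their call with the first normexp correction were Prok2 (1.59), Fbxw13 (1.72), Meis2 (0.46), Msx2 (0.96), Ccne2 (-0.82) and Fas (0.79), with adjusted p from 0.0644 to 0.786. The second normexp fit, made without marked spots, kept these calls. The double knockout and the Cyp26b1 knockout also lay on different slides scanned on different days.

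**Figure D2:**
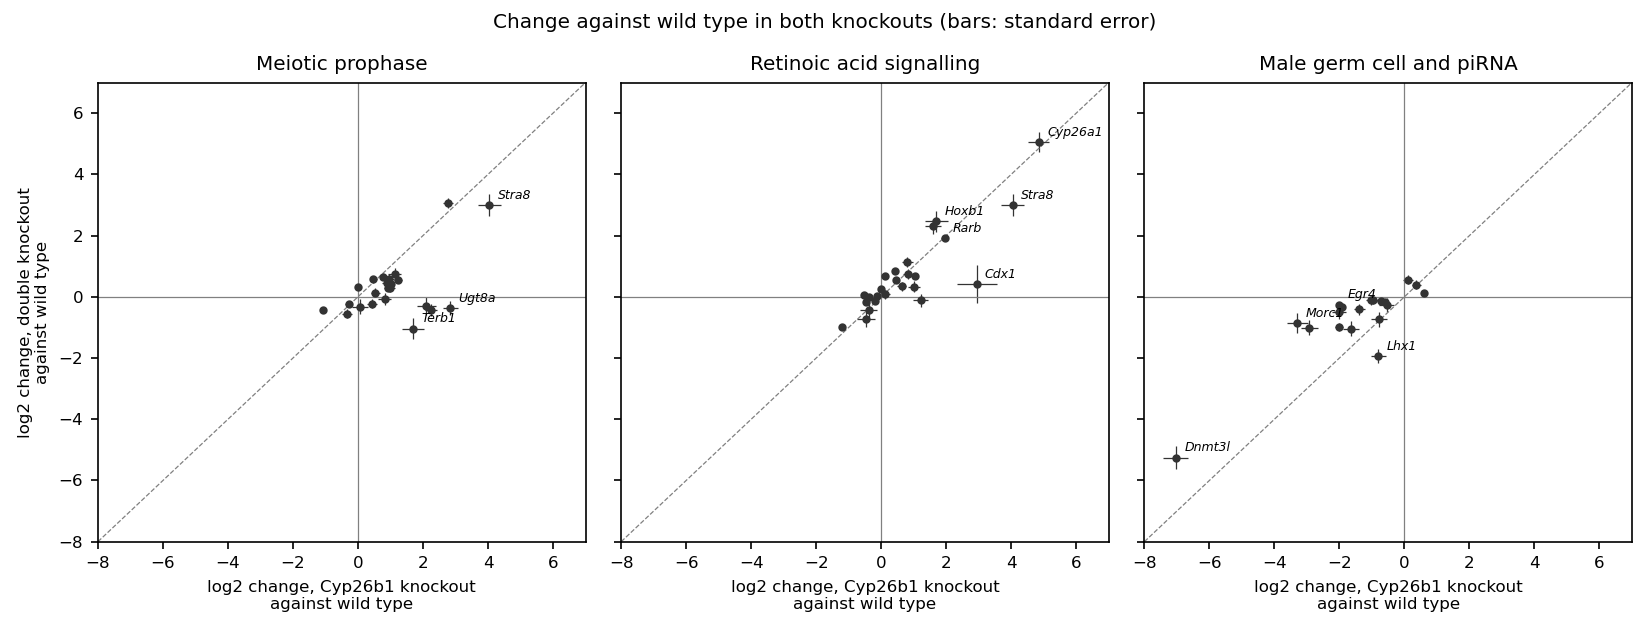
Log2 change against wild type in the Cyp26b1 knockout (horizontal) and in the double knockout (vertical) for the measured genes of 3 lists, including genes not well above background in a genotype and without genes not reported here. Points are genes, bars are standard errors, and the dashed line marks equal changes. Cyp26a1 lies near that line at 4.84 and 5.05, and Ugt8a lies far below it at 2.84 and -0.37. The meiotic gene Rec8 lies near the line at 2.76 and 3.06.

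Calls were then compared between comparisons. In both knockouts 746 features were higher than in wild type and 1164 lower. Independent lists of these sizes would share 250 and 422, and 50 simulations of unchanged genotypes sharing the wild-type arrays, in which almost no feature was called, gave means of 0.02 and 0. Of the features called in the Cyp26b1 knockout, 2980 were higher there than in wild type and the double knockout, and 4211 were lower than in both. Independent lists would share 809 and 1645. Because the 2 arrays of a shared genotype cannot be split, part of the excess may come from the shared arrays. For the 746 and 1164 features these are the wild-type arrays, which alone lay on their slide. For the 2980 and 4211 features these are the Cyp26b1 knockout arrays, which alone lay on their slide and scan day. An effect of the slide, or of the day for the Cyp26b1 knockout, would give the same overlaps. It was not simulated, so it cannot be told apart from genotype. The log2 changes of both knockouts against wild type had a Pearson r across features of 0.599, beside 0.501 in the simulations, and a covariance of 0.271, beside 0.0228. For the Cyp26b1 knockout against wild type and against double knockout, r was 0.759, beside 0.498, and the covariance 0.422, beside 0.0226. Features are not independent replicates. The features shared by both knockouts numbered 217 higher and 212 lower without wild-type replicate 2, and 259 and 293 without wild-type replicate 1. They numbered 461 and 740 without double knockout replicate 1, and 398 and 593 without double knockout replicate 2.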

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

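The second normexp fit, the signal column of the first and the authors' scaling were chosen after the data were seen. The planned slide block could not be fitted because each slide held 1 genotype, so slide and genotype cannot be told apart. Replicate numbers gave correlations of deviations of 0.119, 0.226 and 0.119 between genotypes. The labels tie a number to no shared litter or day and each comparison has only 2 pairs, so pairing was not established. With the replicate block the counts were 4809 higher and 6900 lower for Cyp26b1 knockout against wild type, 1361 and 1699 for double knockout against wild type, and 5970 and 4028 for double knockout against Cyp26b1 knockout. The block moved no list across the threshold, and 1 change of a named gene gained a call. Unless stated, the cause of a difference was not tested. Quantile normalization, the floor, the stricter filter, the 4 arrays compared and the mean of all probes moved no count by over 1.5 times.

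In the order Cyp26b1 knockout against wild type, double knockout against wild type, and double knockout against Cyp26b1 knockout, higher then lower, the first normexp correction called 1619 and 1970, 310 and 207, and 1547 and 1063. The 4 overlaps were 179 higher and 163 lower in both knockouts, and 849 higher and 1045 lower in the Cyp26b1 knockout than in both others. Spots with a local background of up to 35410 against a median of 75 on wild-type replicate 2, and up to 3325 against 76 on double knockout replicate 1, had drawn the fitted background means to -726 and -178. That correction lost 11, 20 and 19 calls of named genes, among them Msh5 (0.63) and Ugt8a (1.19) in Cyp26b1 knockout against wild type. Over the 21552 features tested, which include dim ones, the SD of the difference between wild-type arrays was 1.07, against 0.319 for the processed signal. Fitted without marked spots, these means were -1.47 and -13.4 and the SD was 0.209. The counts were then 5142 and 5673, 1219 and 1234, and 4902 and 3690, and no named gene lost the threshold. In the first correction lists gained calls: general germ cell markers (mean log2 change 0.23 in Cyp26b1 knockout and 0.22 in double knockout against wild type), cell cycle (0.35, 0.18, and -0.17 between the knockouts) and meiotic prophase in double knockout (0.29). The endothelial list lost its call in Cyp26b1 knockout (0.11).

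At 2-fold or more, the counts were 1502 and 2002, 348 and 610, and 867 and 1250, and the overlaps 206, 460, 858 and 641. Median scaling gave 2458 higher in double knockout than wild type and 1285 higher in both knockouts. Under the authors' scaling, 673 were higher and 4319 lower in double knockout than wild type, and 2090 and 7093 than Cyp26b1 knockout. The overlaps were 2563 lower in both knockouts, and 4615 higher and 1830 lower in Cyp26b1 knockout than in both others. That setting only moves each genotype by a constant. The constant alone moved the mean of the general germ cell list in double knockout against wild type from 0.15 to -0.051. With no filter, 743 and 822 were called in double knockout against wild type, 10362 were higher in double knockout than Cyp26b1 knockout, and the first 2 overlaps were 475 and 706. With all probes tested separately, which adds features, 7020 were higher in Cyp26b1 knockout than wild type, 6226 lower in double knockout than Cyp26b1 knockout, and 4973 in the third overlap. Without the eBayes trend, 776 were higher in double knockout than wild type.

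The estimated correlation of the retinoic acid list was -0.010, below the preset 0.01. Its unadjusted camera p nevertheless rose from 0.00106 to 0.0349 in Cyp26b1 knockout and from 6.12e-07 to 0.0113 in double knockout against wild type. That setting is limited to 3 residual degrees of freedom, so a call lost under it does not by itself show correlated genes. Of the list calls, all 9 were lost with an estimated correlation, which leaves the means as they are. These were meiotic prophase (1.05), retinoic acid (0.86), male germ cell (-1.51) and endothelial (0.32) in Cyp26b1 knockout against wild type, retinoic acid (0.85), male germ cell (-0.69) and endothelial (0.30) in double knockout against wild type, and meiotic prophase (-0.74) and male germ cell (0.82) between the knockouts. With fry, calls were gained for Leydig (-0.31), cell cycle (0.22) and inhibitors (-0.31) in Cyp26b1 knockout, and for ovarian somatic (0.35) and inhibitors (0.22) between the knockouts. They were lost for male germ cell (-0.69) and endothelial (0.30) in double knockout. The endothelial call in Cyp26b1 knockout was also lost with median scaling (0.34), the second normexp fit (0.28), the stricter filter (0.30) and the 4 arrays compared (0.32). The cell cycle list gained a call in Cyp26b1 knockout with quantile normalization (0.31), the authors' scaling (0.32) and no filter (0.22), in double knockout with median scaling (0.23), and between the knockouts with quantile normalization (-0.24) and the authors' scaling (-0.42). The authors' scaling also gave calls to meiotic prophase in double knockout (0.11) and ovarian somatic between the knockouts (0.050). Without a filter the male germ cell call between the knockouts was lost (0.66).

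Leaving out each array in turn, where the lone array is assumed to vary like the other genotypes, gave 3062 to 4583 higher in Cyp26b1 knockout than wild type, 272 to 1293 higher and 259 to 1531 lower in double knockout, and 217 to 744 higher and 212 to 1191 lower in both. List means with a changed call ranged from -0.40 to -0.23 (Leydig), 0.17 to 0.26 (cell cycle) and 0.28 to 0.37 (endothelial) in Cyp26b1 knockout, and from 0.21 to 0.40 (meiotic prophase) and 0.051 to 0.25 (germ cells) in double knockout. Of named genes in double knockout against wild type, 22 lost the threshold without wild-type replicate 2 and 15 without wild-type replicate 1. Averaging all probes turned Pdgfra between the knockouts to -0.083 (adjusted p = 0.534), because its probes disagree. Probes near background limit what dim genes can show.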

Other observations

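The 5 lists described first, and the tests of genotype against slide, of the Stra8 probe and of other germ cell markers, were chosen after results were seen, as were the genes named from these lists. In the Cyp26b1 knockout arrays, 15 of 30 measured Hox cluster genes rose and 6 fell (camera adjusted p = 0.0247, and adjusted p = 0.705 with an estimated correlation). In the double knockout 13 rose and 0 fell (adjusted p = 0.00192, and adjusted p = 0.675 with an estimated correlation). Hoxa5 rose by 2.34 and 2.64, and Hoxb4 by 1.28 and 1.45 in the Cyp26b1 knockout and the double knockout. Of 21 motile cilia genes, 11 fell and 2 rose in the Cyp26b1 knockout (adjusted p = 0.0146, and adjusted p = 0.705 with an estimated correlation) and 8 fell and 1 rose in the double knockout (adjusted p = 0.00192, and adjusted p = 0.675 with an estimated correlation). Among them Drc1 changed by -4.60 and -2.18, and Tekt1 by -2.92 and -1.41. Pifo and Dnah5 were not well above background in the knockouts, and were at least 5.86-fold and 3.81-fold lower in the Cyp26b1 knockout and at least 3.56-fold and 2.39-fold lower in the double knockout. Between the knockouts, 8 Hox genes rose and 6 fell (adjusted p = 0.993), and 7 cilia genes rose and 3 fell (adjusted p = 0.171).

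Of 6 measured Rhox genes, 5 rose in the Cyp26b1 knockout (adjusted p = 0.000798, and adjusted p = 0.570 with an estimated correlation), 2 rose in the double knockout (adjusted p = 0.0148, and adjusted p = 0.675 with an estimated correlation) and 4 fell between the knockouts (adjusted p = 0.00330, and adjusted p = 0.901 with an estimated correlation). These genes have near-identical copies and are uncertain. Oocyte genes went both ways, with 6 of 16 higher and 6 lower in the Cyp26b1 knockout (adjusted p = 0.701). Sohlh2 (3.97) and Figla (1.73) rose, while Padi6 fell (-3.92, well above background on 1 of 2 arrays) and Zp3 was at least 3.11-fold lower. In the double knockout 5 rose and 3 fell (adjusted p = 0.478), with Figla at 1.87 and Lhx8 at 3.52, and between the knockouts 3 rose and 4 fell (adjusted p = 0.993). Of 21 steroid and cholesterol synthesis genes, 5 rose and 9 fell in the Cyp26b1 knockout (adjusted p = 0.701), and 0 rose and 1 fell in the double knockout (adjusted p = 0.0328, and adjusted p = 0.675 with an estimated correlation). Between the knockouts 8 rose and 6 fell (adjusted p = 0.993).

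Far more features differed from wild type in the Cyp26b1 knockout than in the double knockout, 51.2% against 12.0%. A different signal distribution on that slide would be removed by quantile normalization, but 11133 features were still called then, against 2465 for the double knockout, a ratio of 4.52. The contrast was smaller under other scalings. Median scaling called 4602 higher and 6048 lower, against 2458 and 1004 for the double knockout. The authors' scaling called 5579 and 5216, against 673 and 4319. Changes of single probes between slides would not be shared by different probes of a gene, and across 4031 genes the Spearman rho of 2 probes was 0.442 (bootstrap interval 0.415 to 0.468), between the bounds set beforehand, so probe-specific changes may be part of the pattern. This correlation was 0.404 (0.375 to 0.431) for the other comparison with the Cyp26b1 knockout slide and 0.572 (0.548 to 0.598) for the double knockout against wild type, beside 0.00426 to 0.0232 with a probe of another gene. With 0 slides or scan days holding the Cyp26b1 knockout and another genotype, genotype, slide, scan day and the tissue collected cannot be told apart.

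The Stra8 probe was brighter in the double knockout arrays than in wild type, and if those arrays held Cyp26b1 knockout RNA, the other meiotic genes would not differ between them. The median change of 22 such genes was -0.42, at percentile 0.01 of 10000 random lists matched on level, the lowest these lists can give. Random lists treat genes as independent. With an estimated correlation, a camera setting limited to 3 residual degrees of freedom, this list had p = 0.129. Across 18971 features, double knockout arrays differed from Cyp26b1 knockout arrays with SDs of 0.604 to 0.635. They differed from wild-type arrays with SDs of 0.447 to 0.491, and arrays of one genotype with SDs of 0.243 to 0.298. These values argue against such an exchange for these arrays. The Cyp26b1 knockout and double knockout also lay on different slides and scan days, so the exchange was not excluded. A transcript of the targeted allele that still holds the probe sequence may remain, but the array has 1 Stra8 probe, so this cannot be told apart from other sources of signal.

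Of 19 male germ cell genes, 15 fell and 1 rose in the Cyp26b1 knockout arrays, with a median of -1.02 for the list. The list had a camera adjusted p of 0.000231 (adjusted p = 0.426 with an estimated correlation). A loss of germ cells would lower other germ cell markers by about as much. The 17 markers outside the male and meiotic lists had a median of 0.41 (bootstrap interval -0.44 to 1.07), with 8 higher and 4 lower, against a bound of -0.51. That interval lay above the bound but treats the markers as independent. Widened for the estimated correlation of these markers the interval was -1.57 to 1.95. The widening applies a correlation of residuals between arrays to a spread between markers, so it is only a rough allowance. This test therefore could not tell fewer germ cells apart from other explanations. A change of germ cell state with genotype may be an explanation, but it stays untested because of the slides.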
